A study of Reaumuria songarica with 2 samples.

How the data were processed

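Digital gene expression tag profiling was carried out on leaf RNA of Reaumuria songarica, with 1 library from plants kept outdoors and 1 library from plants that received supplementary UV-B. Per the labels' protocols, polyadenylated RNA was captured on oligo(dT) beads, copied into cDNA and cut with NlaIII, an enzyme that cuts at CATG. The fragments left on the beads were ligated to an adaptor and cut with MmeI, which leaves a tag of CATG and 17 further bases that lies at the NlaIII site nearest to the poly(A) tail.

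The deposited values are raw counts, the number of copies of each 21-base tag, per the file headers. The 2 lists are those the submitters named as unmatched tags, so each holds part of a library and its sum is not the sequencing depth. The reference that the tags were compared with, the mismatches allowed and the read filter are not given in the sources used here. The smallest count listed was 2 copies in both libraries, so a tag that a list leaves out had 0 or 1 copies, or was removed in another way. The tags that did match were not analysed here, nor was any genome or transcript set. The lists pair no tag with a gene, so tags are named by their sequence, and the gene groups chosen beforehand (flavonoid synthesis, UV-B signalling, DNA repair, antioxidants, photosynthesis, chaperones and pathogenesis-related genes) were not tested.

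Samples were grouped by their treatment labels. The listed copies numbered 1156678 in the untreated library and 1586036 in the UV-B library. Levels are copies scaled to a list total of 1000000 (CPM of the copies listed), which differ from a level relative to all sequenced tags by an unknown factor. That factor can differ between the libraries. Every ratio below, and the balance of higher and lower tags, may therefore be shifted against ratios relative to all sequenced tags. In these units, 2 copies were worth 1.73 in the untreated library and 1.26 in the UV-B library. With 1 library per group there was no spread between replicates to measure. Intervals therefore cover counting error only, compare these 2 libraries and not the conditions, and carry no p-value. Tags amplified by PCR without molecular identifiers are not independent molecules.

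The ratio of a tag's levels (UV-B over untreated) was given an exact 95% conditional (Clopper-Pearson) interval for 2 Poisson counts. Tags with at least 20 copies over both libraries were compared. A tag was counted as higher when its whole interval lay above 2-fold and as lower when its whole interval lay below the inverse of 2-fold. An unlisted tag entered at 1 copy. The fold of a tag listed in 1 library only is given as the lower end of this interval. Shares of copies have exact Clopper-Pearson intervals. Agreement between the libraries was measured as Pearson and Spearman correlation across tags of log2(CPM + 1), and tags are not replicates.

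Tags were classed by sequence: a second CATG or a GATC within the 17 bases, a run of at least 8 A or 8 T, at most 2 different bases, at least 8 bases of an Illumina tag adaptor, GC content of the 17 bases under 30%, from 30 to 50% or over 50%, and 1-base neighbours of a tag at least 50 times as abundant in the same library. The median log2 ratio of a class was placed among 10000 random lists of the same size matched on mean level in 20 bins. A further class, tags ending in 5 or more A, was added after the data had been examined. Intervals of medians come from 2000 resamplings of tags.

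The tags named below were chosen by a rule fixed before the data were examined, as were the tests and classes except where stated. They are the 5 most abundant tags of each library, the 6 higher tags with the largest lower bound, the 6 lower tags with the smallest upper bound, and the 3 tags with most copies in each library that the other did not list. None of the tags so named was of low complexity or a 1-base neighbour of a tag at least 50 times as abundant. The most abundant of them could not be such neighbours, since no listed tag was 50 times as abundant.

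The ratio calls were tested on simulated data, with libraries drawn from the pooled tag rates and 200 tags changed. Changed tags were drawn only from those with at least 100 copies over both libraries, as 3688 of the 17245 tags compared had. Recovery among tags with fewer copies was not simulated. Of 17605 tags tested, the calls recovered 49 of 50 tags simulated 4-fold higher, 50 of 50 tags 8-fold higher, 49 of 50 tags 4-fold lower and 49 of 50 tags 8-fold lower, with 1 false call. Alternatives were other scalings (median of ratios, and TMM factors from edgeR 4.0.16), other minimum copies, other fold bounds, an interval widened for the number of tags, neighbours left out, the 10 most abundant tags left out and the larger library thinned to the size of the smaller. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3, and plots were drawn with matplotlib 3.10.9.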

Results

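Reaumuria songarica is a salt-secreting desert shrub of the tamarisk family. To find transcripts that differ in leaves of UV-B stressed plants, 1 tag library was made from plants under natural conditions and 1 from plants given supplementary UV-B, which the labels put at 0.2 W. Only the tags listed as unmatched were analysed. They are 21-base sequences next to the last NlaIII site of a transcript, each with its number of copies. The untreated library listed 101802 distinct tags with 1156678 copies, and the UV-B library listed 101852 distinct tags with 1586036 copies, 1.37 times as many copies. There were no replicates, so each value below is from a single library and has no replicate check.

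A few tags held much of each list. Tags with 100 or more copies numbered 1441 in the untreated library (1.42% of its distinct tags) and held 43.4% of its copies. In the UV-B library 2100 such tags (2.06%) held 53.3% of the copies. The cut of 100 copies is a lower level in the larger UV-B list, so part of this difference follows from list size. The 10 most abundant tags alone held 8.46% of the untreated copies and 12.4% of the UV-B copies. At the other end, tags with 2 copies, the fewest listed, made up 42.0% of the distinct tags in the untreated library and 37.7% in the UV-B library.

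The most abundant tag was the same in both libraries. CATGGACTTGTGGTTAAAAAA, which runs into 6 A bases at its 3' end, had 37008 copies in the untreated library (31995 CPM, copies scaled to a list total of 1000000, 95% counting interval 31670 to 32323) and 67977 in the UV-B library (42860 CPM, 42538 to 43183), a ratio of 1.34 (interval 1.32 to 1.36). CATGCTTTCGTTCAAAAAAAA was second in both, with 10324 and 24693 copies and a ratio of 1.74 (1.70 to 1.79). CATGTTGTTTAAAAAAAAAAA had 9061 and 15452 copies, a ratio of 1.24 (1.21 to 1.28). These 3 tags were among the 5 most abundant of each library, and none of them passed the 2-fold bound. The other two of the untreated library were at lower levels in the UV-B library. CATGAGAAGTACTCTTTATTG had 9084 copies untreated and 7265 with UV-B, a ratio of 0.583 (0.565 to 0.602). CATGTCGGACTGTAGAACTCT had 7758 and 2224 copies, which made it 4.78-fold lower in the UV-B library (4.56 to 5.02) and past the bound. The other two of the UV-B library were higher there and past the bound. CATGCTTAAGTTTCGGATATT had 5714 copies untreated and 23368 with UV-B, 2.98-fold higher (2.90 to 3.07). CATGGAGCAGATAATGTGAAT had 3702 and 21302 copies, 4.20-fold higher (4.05 to 4.35).

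Of the 157489 distinct tags in the 2 lists, 46165 (29.3%) were listed in both. The share was 66.6% among tags with at least 5 copies in either library and 90.0% (11467 of 12742) among those with at least 20. The 46165 shared tags held 83.1% of the untreated copies and 86.0% of the UV-B copies. The levels of the 15970 shared tags with at least 20 copies summed over both libraries correlated across tags, with a Pearson r of 0.62 and a Spearman rho of 0.47. Both values depended on the minimum of copies. Among the 1050 tags with 100 or more copies in each library, the log2 ratio had a median of -0.01 and a standard deviation across tags of 0.93. Counting error alone gave 0.14 in libraries drawn from 1 set of rates. In this set 781 tags (74.4%) were within 2-fold, but a minimum in each library leaves out tags that differ most. For the 3570 shared tags with 100 or more copies over both, the median difference of log2(CPM + 1) was 0.18 and its standard deviation 1.34.

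The comparison of the UV-B library with the untreated library covered 17245 tags with at least 20 copies over both. The whole ratio interval lay above 2-fold for 1532 tags (8.88%) and below the inverse of 2-fold for 1861 tags (10.8%), and 13852 tags (80.3%) passed neither bound. Many calls rest on a tag that 1 library did not list, entered at 1 copy: 706 of the higher and 569 of the lower tags. Among tags listed in both libraries, a limit added after the data were examined, 826 were higher and 1292 lower. The 1532 higher tags held 4.09% of the untreated copies and 17.9% of the UV-B copies. The 1861 lower tags held 17.2% of the untreated copies and 3.02% of the UV-B copies. Libraries simulated with no change gave 1 call among 17571 tags, so the calls lay far beyond counting error. Whether they lie beyond the spread between plants was not measurable with 1 library per group.

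**Figure D1:**
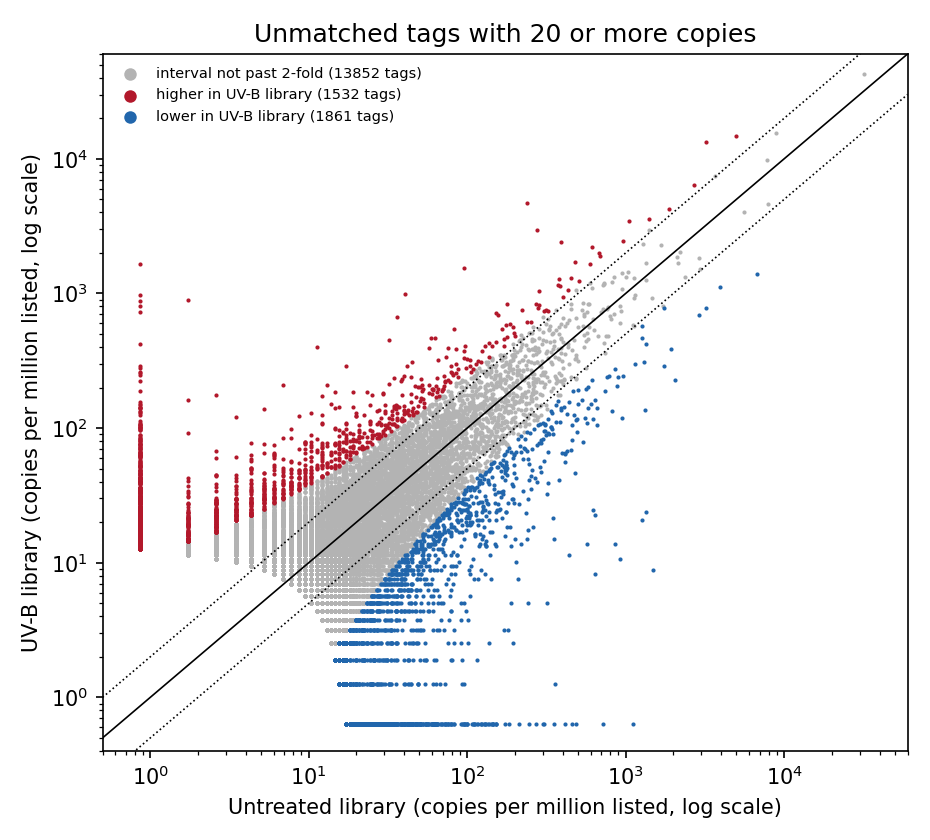
Each point is 1 of the 17245 tags with at least 20 copies, at its level in the untreated library (x axis) and in the UV-B library (y axis), both in CPM of the copies listed, on log scales, with unlisted tags drawn at 1 copy. The solid line marks equal levels and the dotted lines mark 2-fold. The 1532 tags called higher in the UV-B library are red, the 1861 called lower are blue, and the leftmost column and lowest row of points are tags listed in 1 library only.

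The largest differences were in tags that 1 library did not list at all. For these, the fold given is the lower end of the ratio interval with the unlisted tag at 1 copy, and it is no bound if the tag was removed from the list in another way. CATGTGGAAGATTGTTGATGT had 2609 copies in the UV-B library (1645 CPM) and was not listed in the untreated one, with a lower end of 341-fold. CATGTATTTGAATCATATTAC had 1546 UV-B copies and was unlisted in the untreated library, with a lower end of 202-fold. CATGTATTTGAATCAAAAAAA shares its first 15 bases with that tag and differs after them. It had 2 copies untreated and 1425 with UV-B, a ratio of 519.6 with a counting interval of 144 to 4295. CATGTAAATTAAACAAAAAAA (1382 copies, lower end 181-fold), CATGCATACTCAGGTCATTTG (1283 copies, 168-fold) and CATGTAAATTAATCAAAACTC (1156 copies, 151-fold) were likewise listed only in the UV-B library. The first of these differs by 1 base from CATGTAAATTAATCAAAAAAA, a tag chosen after its values were seen. That tag had 3110 copies untreated and 10140 with UV-B, 2.38-fold higher (2.28 to 2.48). It also shares its first 18 bases with the last of these, the tag with 1156 copies. A tag with the same start was thus abundant in the untreated library.

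In the other direction, CATGCACTATAGTTCAGTCCT had 1724 copies in the untreated library and 14 in the UV-B library, 169-fold lower (100.4 to 309.5). CATGGTTCCGTGATTTCTGGC had 1281 copies untreated (1107 CPM) and was not listed with UV-B, lower there with a lower end of 315-fold. CATGTGGACTACCTACTAAAT had 830 untreated copies and a lower end of 204-fold. CATGTTCAGGCTATGTAAACA had 561 copies and a lower end of 138-fold. CATGGTTATCCGTTCCCCCTC, with 531 copies, and CATGGGCAAATGAATGTTTTC, with 477, had lower ends of 130.1-fold and 117-fold, and none of these 5 tags was listed with UV-B. The tag with 531 copies shares at least its first 10 bases after CATG with a tag that runs into A bases. That partner had 1484 copies untreated and 3702 with UV-B. Whether both come from 1 transcript was not tested. Of all tags with 50 or more copies in 1 library, 158 were listed only in the untreated and 165 only in the UV-B library, 4.43% of the 7296 tags with that many copies over both. At 20 or more copies the numbers were 569 and 706.

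The libraries also differed in the make-up of their tags. Tags with a run of 8 or more A, which sit next to the poly(A) tail or on an A-rich stretch, held 9.41% of the untreated copies (interval 9.35 to 9.46%) and 16.7% of the UV-B copies (16.7 to 16.8%), a ratio of shares of 1.78 (1.77 to 1.79). Of the 2087 such tags compared, 248 were called higher and 20 lower. Their median log2 ratio was 0.89, above all 10000 random lists of like level, the highest of which reached 0.28. The median of all 17245 tags was 0.13. Tags ending in 5 or more A, a class added after the data were examined, held 20.1% and 33.9% of the copies, and 424 of the 3836 compared were called higher against 41 lower.

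Tags rich in G and C were lower in the UV-B library. The mean GC content over copies was 32.5% untreated and 28.4% with UV-B. Tags over 50% GC held 11.3% of the untreated copies (11.2 to 11.3%) and 5.75% of the UV-B copies (5.72 to 5.79%), and of the 1464 compared 393 were called lower and 88 higher. Their median log2 ratio of -0.84 was below all 10000 random lists, the lowest of which reached -0.05. Tags of 30 to 50% GC had a median of -0.25, with 865 of 5888 called lower and 480 higher, and this median too was below all random lists. Tags under 30% GC had a median of 0.44, with 964 of 9893 called higher and 603 lower, above all random lists.

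**Figure D2:**
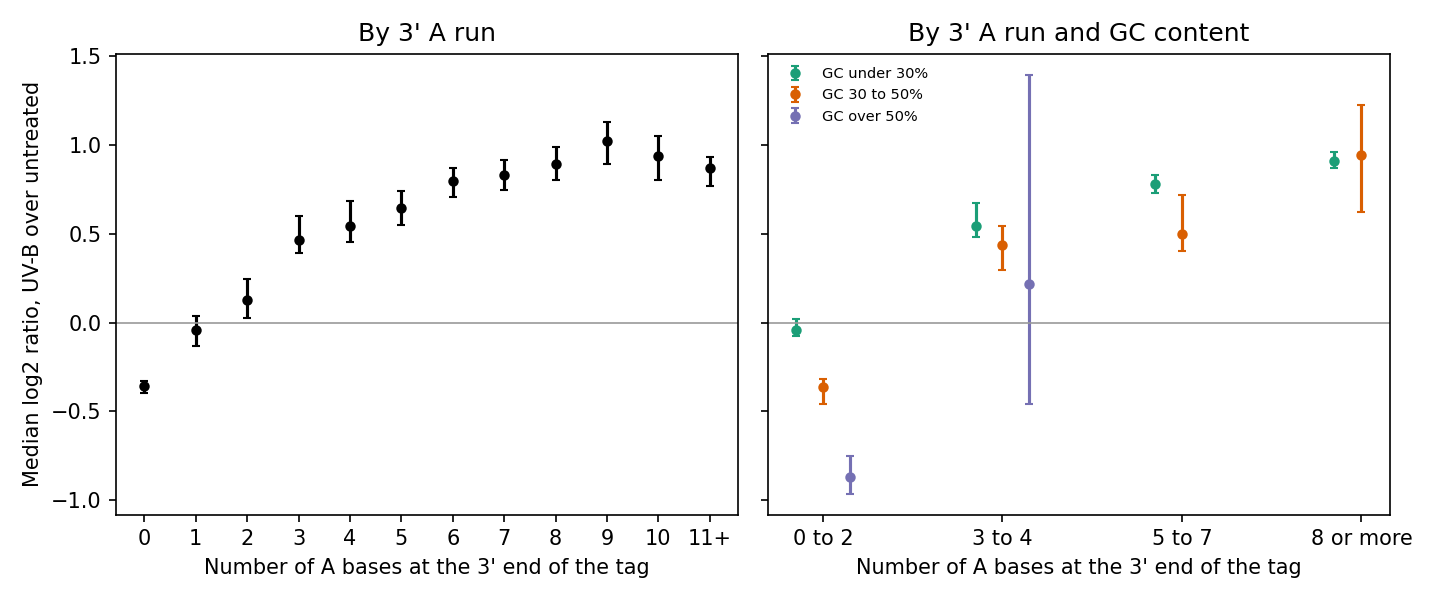
Points are the median log2 ratio (UV-B over untreated) of tags with at least 20 copies, by the number of A bases at the 3' end of the tag (left) and by that number and GC content (right, classes with fewer than 20 tags left out). Bars are 95% intervals from resampling tags, which are not replicates. The median was -0.35 for tags ending in no A and 1.02 for tags ending in 9 A.

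The median log2 ratio was higher for tags with more A bases at the 3' end, up to 9 A. It was -0.35 (interval -0.39 to -0.33) for the 9099 tags ending in another base, 0.47 (0.39 to 0.60) for tags ending in 3 A, 0.83 (0.75 to 0.91) for 7 A and 1.02 (0.89 to 1.13) for 9 A. Tags ending in 11 or more A had a median of 0.87 (0.77 to 0.93). Within tags ending in 0 to 2 A, the median was -0.04 under 30% GC, -0.36 from 30 to 50% and -0.87 over 50%. Within tags ending in 5 to 7 A it was 0.78 under 30% GC and 0.50 from 30 to 50%, and within tags ending in 8 or more A it was 0.91 and 0.94, the latter over 26 tags (interval 0.62 to 1.22).

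The remaining classes were small. Tags with a second NlaIII site inside, which mark a site the enzyme left uncut, held 0.465% of the untreated copies (0.452 to 0.477%) and 0.547% of the UV-B copies (0.536 to 0.559%). Their median log2 ratio of 0.47 lay at the 91.2 percentile of the random lists. Tags with a GATC, the DpnII site, held 3.15% and 3.02%, and their median of 0.13 lay at the 46.4 percentile. Tags with a run of 8 or more T held 0.430% and 0.331%, with a median of -0.08 at the 20.4 percentile. Low-complexity tags held 0.452% and 0.746%, and their median of 0.79 lay above all random lists. Neighbours by 1 base of a tag at least 50 times as abundant held 0.518% and 0.847%, with a median of 0.61 at the 99.9 percentile. Sequence of the tag adaptor was found in 2 tags with 17 copies in the untreated library and in 0 tags listed in the UV-B library.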

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

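The calls of 1532 higher and 1861 lower tags stayed within 1.5 times under both other scalings, with neighbours left out, with the 10 most abundant tags left out of the totals, and after thinning. In settings chosen after the data were seen, there were 1249 higher and 1861 lower with an unlisted tag at 3 copies, with ratios centred by GC class and 3' A run 1385 and 1519 (1139 and 1427 of them among the 1532 and 1861), and, by testing fewer tags, 1108 and 1820 without A-ended tags and 826 and 1292 among tags listed in both libraries. An unlisted tag at 0 copies could change no call, since all 706 and 569 unlisted tags were called at 1 copy. TMM scaling lowered every log2 ratio by 0.12, and the median of all compared tags went from 0.13 to 0.01. A minimum of 50 copies left 759 higher and 900 lower tags and a minimum of 100 copies 433 and 465, by testing fewer tags. With no minimum 1662 were higher and 2989 lower. A bound of 1.5-fold gave 2505 higher and 2690 lower, a bound of 4-fold 421 higher and 892 lower, and intervals widened for the number of tags 303 and 612. Shared tags were 11467 of 12742 with at least 20 copies in either library, against 46165 of 157489, so their number fell and their share rose from 29.3% to 90.0%. Distinct tags with at least 5 copies were 32951 of 101802 untreated and 37840 of 101852 with UV-B. The Pearson r of 0.62 was 0.588 with a pseudocount of 0.1, 0.715 with 10, 0.488 at a minimum of 100 copies and 0.773 with none, and the Spearman rho of 0.47 was 0.383 and 0.632 at those minimums; the cause was not tested. Without the 10 most abundant tags the ratios of shares moved to 1.91 for A runs (from 1.78), 1.24 under 30% GC (from 1.23), 0.825 from 30 to 50% (from 0.810), 0.535 over 50% (from 0.511), 1.23 for a second NlaIII site (from 1.18) and 1.86 for A-ended tags (from 1.69). The ratio for GATC tags turned from 0.958 to 1.003. Leaving out the 10 tags took the ratio of list totals, UV-B over untreated, from 1.37 to 1.31. That change in totals accounts for the turn, so it is no change in the GATC tags. No replicate could be left out, gene groups were not run for want of a transcript set, and a library total was not given, so copies listed set the scale. Of 60 values of named tags under other scalings, 45 stayed inside their counting interval. The intervals of tags unlisted or nearly absent in 1 library are too wide for such shifts to leave. The 15 values that left their interval were all of abundant tags listed in both libraries, under TMM or without the 10 most abundant tags. For the most abundant tag, TMM moved the log2 ratio from 0.42 to 0.30. Its counting interval is thus narrower than the shift between scalings.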

Other observations

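The tests of GC content, of GC within tags lacking 3' A, of the difference within tag pairs, of longer shared starts, of sequencing errors and of 1-base relatives were chosen after the values they use had been seen. The tests of digestion by pooled odds, of counting chance and of the correlation of pairs were written down first. The odds ratio within sites and the digestion values without the most abundant tag were not among those written down first.

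Some tags shared their start but not their end. Among tags with at least 20 copies, 616 pairs shared the first 10 bases after CATG but had different ends: 1 tag ran into at least 5 A, and its partner went on with at least 3 different bases. Shuffling the bases of each A-ended start gave 136 such pairs on average (158 at most in 20 draws). With the first 12 bases shared there were 309 pairs, and shuffling gave 23 at most. No transcript set was used, so a pair can come from 1 transcript or from related genes. CATGACATTTAATCTTAAAAA had 948 copies untreated and 1928 with UV-B, and its partner CATGACATTTAATCTTAATTT had 1094 and 2243. CATGTTACTTGATCAAAAAAA had 13 and 631 copies, and CATGTTACTTGATCAATTGCC had 3 and 278. Pairs that moved apart were also present: CATGCCCTTCTTTACAAAAAA had 32 and 216 copies, and CATGCCCTTCTTTACACACAC had 320 and 193. These pairs were chosen as examples after their values were seen. Gaps were wider for some tags named above, with an unlisted tag at 1 copy. The tag with 531 untreated copies had a log2 ratio of -9.51, and its A-ended partner 0.86. The tag with 1156 UV-B copies had 9.72, and its A-ended partner 1.25. The tag with 1546 UV-B copies and its A-ended partner moved together, at 10.14 and 9.02.

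If a ratio belongs to the transcript and not to the single tag, such partners should move together. The log2 ratios of the 616 pairs had a Spearman correlation of 0.51 across pairs, while 10000 random pairings within the same GC content of the start reached 0.16 at most, with a median of 0.01. The pairs are not replicates, and the result bears only on differences between these 2 libraries. Over the 309 pairs with 12 shared bases the correlation was 0.61. Partners would move together in this way if many tag ratios reflect the abundance of a transcript in each library. The random pairings were matched only on GC content, so a bias tied to the shared bases is not excluded. Nor does the result say whether UV-B or another difference between the plants set that abundance.

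The higher level of A-ended tags in the UV-B library was not accounted for by the GC content of the tags: at 30 to 50% GC, A-ended tags were above other tags by 0.86 in median log2 ratio (interval 0.75 to 1.07). Within the 616 pairs the A-ended tag exceeded its partner by 0.79 (0.67 to 0.87) and was the higher in 471 pairs (76.5%), and within the 309 longer pairs by 0.68 (0.57 to 0.83). Whether other transcripts were expressed stays open, since partners from related genes are not excluded. Incomplete NlaIII digestion of the untreated library should leave more uncut second sites there. The odds of reading through a second site, pooled over 376 tags, were 0.986 times as high in UV-B as in untreated (0.944 to 1.03). Without the most abundant such tag this was 0.920. Within sites the odds ratio over all of these tags was 1.69 (1.18 to 2.24), toward more reading through in UV-B. Without that most abundant tag the ratio within sites was 1.36. Pooled odds also shift with the make-up of the lists. Copies starting at second sites numbered 167196 untreated and 319487 with UV-B. Such copies were recognised by the bases left in the tag after its second site, 9 at the fewest, so accidental agreement is not excluded. Tags of either kind that matched the reference are missing here, so the test does not exclude a difference in digestion. The low level of GC-rich tags was not accounted for by the A-ended tags. Among tags with fewer than 3 A at the end, those over 50% GC differed from those under 30% by -0.83 in median log2 ratio (-0.94 to -0.71). Among tags ending in 3 to 4 A, the median was 0.54 under 30% GC. Over 50% GC it was 0.22 (-0.46 to 1.39), over 25 tags. A cause shared by both patterns is not excluded. Amplification bias by GC, RNA integrity, earlier poly(A) sites and the UV-B treatment itself stay open and untested, with 1 library each.

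The 323 tags with 50 or more copies in 1 library and none listed in the other are too many for counting chance, as libraries drawn from 1 set of rates gave 0. Of these tags 0% (upper bound 1.14%) differed by 1 base from a listed tag at least 50 times as abundant, as errors of such a tag would. Few listed tags were abundant enough to be such a source for a tag with 50 or more copies. The 0% was thus largely set by that threshold, and its bound says little about errors. Sequence variants between the plants of the 2 libraries would give 1-base relatives, and 20.4% (16.2 to 25.2%) of these tags had one, against 24.4% of tags of like abundance listed in both libraries. Neither share decides, because a source tag or relative that matched the reference would be missing from these lists, so sequencing errors, variants between plants and the effect of UV-B cannot be told apart for these tags.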
